A study of Mus musculus with 6 samples.

How the data were processed

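Gene expression was measured in 3 samples of the mouse embryonic fibroblast line 10T1/2, numbered 1, 4 and 5 in the labels, each on 1 Affymetrix MOE430A and 1 MOE430B array. Per the labels, total RNA was prepared with an RNeasy kit, 5 µL at 100 ng/µL was supplied per sample, and the target was labelled with biotin. The number of amplification rounds is not given in the sources used here. The authors deposited 1 signal intensity per probe set and array, computed with MAS5, per the submitters' processing notes. Its version and settings are not given in the sources used here. The deposited intensities are on a linear scale, and each array was scaled on its own. After trimming 2% at each end, the mean was 1501 on each MOE430A array and 1500 on each MOE430B array. The deposited tables carry no detection calls. The deposited run settings of each array are text and scores of the fluidics station and scanner, per the file headers, and were used only to check the array design, the sample and the run conditions. 0 columns of per-sample values were left unused.

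The 2 array designs were analysed separately throughout, because their arrays were scaled separately. Gene symbols came from the probe set tables of the 2 designs, matched to RefSeq symbols of the assembly GRCm38.p6. The intensity tables name no genome build, so no coordinates are given. Of the 22690 probe sets of MOE430A, 20393 named 1 gene, 691 named several and 1606 named none. Of the 22575 of MOE430B, 14674 named 1 gene, 245 several and 7656 none. Only probe sets naming 1 gene were used for genes, which gave 18194 measured genes.

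Background was set on each array as the 95th percentile of the signals of a list of 104 genes restricted to tissues far from fibroblasts, such as liver, pancreas, retina and pituitary, of which 96 were measured. They gave 125 probe sets on MOE430A and 19 on MOE430B. A probe set was called detected when above this limit on 3 of 3 arrays, and a gene when any of its probe sets was, so a gene given as not detected can be above the limit on 1 or 2 arrays. By this rule 4 genes of the background list itself were detected, Gdf9, Hcrt, Lor and Oxt. The error of the limit was taken from 2000 resamplings of the background probe sets.

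Gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. There were 32 lists of genes beside the background list. For each, the number of detected members was set against 10000 random lists of the same size, matched on the number of probe sets per gene in 4 classes, which is a permutation of the gene labels within a class. A list was called high or low outside the central 95% of the random lists, where 5% lie by chance, and p-values were two-sided and adjusted with the Benjamini-Hochberg method over the 32 lists. Members of a list are regulated together and are not replicates, so these p-values describe these samples only. Signals were set to at least 1 before taking log2. For differences between samples, each list's median log2 deviation of 1 sample from the mean of the other 2 was taken over at least 5 detected members. It was set against 10000 random lists matched on decile of mean log2 signal, and the p-values were adjusted over the lists and samples of a design.

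To separate RNA samples from single arrays, the deviation of each gene from the mean of the 3 samples was correlated between the designs across genes. Genes with a detected probe set on both designs entered, by their brightest probe set, without the 164 probe sets common to both designs. The two-sided p-value came from 10000 permutations of the gene labels, and so did the range for shared signs, a test chosen after seeing the data. The 100 common probe sets that are not controls gave the offset between the designs in each sample. Ratios of 3' to 5' probe sets were taken for Gapdh and beta-actin and, as an added check, for the bacterial poly-A control transcripts.

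The genes named are the first 3 of every list as written, whatever their values, and up to 3 measured members per list that differ from the list's majority call. To these were added the 5 genes with the largest range on both designs, the 10 most variable detected probe sets and the 10 brightest probe sets of each design. A gene is given by its detected probe set of highest mean log2 signal, or its brightest where none is detected. No probe set's level is set against that of another as an abundance. Among the first 3 genes of the lists, Ly6a, Runx2, Bglap, Ccnb1, Trp53, H19 and Rpl3 had no probe set naming them alone and were not analysed here, and some others are not reported here. Genes outside the rule are named as chosen after their values were seen.

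Alternatives covered the limit at the 90th and 99th percentile, detection on 2 of 3 arrays, detection of most probe sets of a gene, removal of probe sets that can match several transcripts, quantile normalisation, pseudocounts of 16 and 64, no filter on dim probe sets, the median signal of a list, and each sample left out in turn. Detection on 2 of 3 arrays for the lists, a filter on the mean signal over the samples, signals below the limit raised to it, leaving out samples in the comparisons between samples, and every alternative for probe sets differing over 4-fold and for the added lists were chosen after seeing the data. The number of arrays, 3 per design, limits the precision. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

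The procedures were tested on simulated data, made from the measured genes for the lists and from normal draws for the shared deviations. In the tests of deviations the noise was drawn for each gene independently, so their rates do not cover lists whose members are regulated together. For detected members, over 18194 genes, 3% of 200 random lists of 20 were called, and lists whose detected genes were drawn 2 times as often were called high in 20% of 200 draws. For list deviations, over 4163 genes, a shift of 1 log2 unit was called in 100% of 100 lists with a mean estimate of 1.00, and unshifted lists in 4% of 300. For deviations shared between the designs, over 341 genes, a shared part of 0.5 was called in 100% of 150 draws with a mean correlation of 0.50, and 4.67% of 150 draws with none shared were called.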

Results

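Expression was profiled in 10T1/2, a line of mouse embryonic fibroblasts that can be turned in culture into muscle, fat, cartilage and bone cells. The cells grew in DMEM with 10% fetal bovine serum and were collected at 80% confluency. RNA of 3 samples, numbered 1, 4 and 5, was hybridised to 1 MOE430A and 1 MOE430B array each, which gave 6 arrays and 1 group. The stated aim was to learn which genes these fibroblasts have in common with stem cells, so that such genes can be taken out of stem cell profiles. On MOE430A the median signal was 581, 557 and 527 in samples 1, 4 and 5, the background limit 1031, 1045 and 909, and 33.8%, 33.6% and 36.3% of the 22690 probe sets lay above it. On MOE430B the median signal was 921, 866 and 856, the limit 2680, 2123 and 2516, and 17.4%, 22.7% and 18.2% of 22575 probe sets lay above it. The labels do not say whether the samples were separate cultures, so the spread between them may be technical and the p-values describe these samples only. Signals are given below as mean ± SD (n = 3) unless the 3 samples are given singly.

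The first comparison asked which genes and gene groups the cells expressed above background. Genes of the fibroblast matrix, of protein synthesis and folding and of basic metabolism were detected far more often than random genes, and the network of pluripotent stem cells far less often. Of 18194 measured genes, 5820 (32.0%) were detected. Detection rose with the number of probe sets per gene, from 18.7% of genes with 1 to 61.3% with 4 or more. The 3' to 5' ratios given below were high, and how far this lowered detection was not tested. A gene not detected was thus not shown to be absent. None of the 3 core regulators of pluripotency was detected, with Pou5f1 at 98.1 ± 69.8, Nanog at 30.2 ± 15.9 and Sox2 at 266 ± 128. Among matrix genes the type I collagen chain gene Col1a2 was detected, at 129321 ± 74976.

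Of the pluripotency network, 1 of 25 measured genes was detected, against a mean of 7.18 in random lists (adjusted permutation p = 0.00640). The exception, the orphan nuclear receptor gene Esrrb, read 4034 ± 624 on MOE430B, from 1 of its 3 probe sets. The other stem cell lists lay within the range of random lists. Among the genes named below, Rest and Eya4 were each detected by 1 of 4 probe sets, Itgav by 1 of 5 and Nes by 1 of 3. Alcam was detected by 4 of 5 and Vim by 3 of 3. Reprogramming and self-renewal factors had 7 of 20 genes detected. Klf4 (4226 ± 1635), Smad1, a mediator of BMP signals, Il6st, the shared receptor chain of the LIF and interleukin-6 family, and the repressor of neuronal genes Rest were among these, whereas Id1 and the growth regulator Myc were not. Myc read 522, 370 and 2827 in samples 1, 4 and 5. Mesenchymal stromal surface markers had 9 of 20 detected, among them the tetraspanin gene Cd81 (20361 ± 5562), the adhesion molecule gene Alcam and the integrin gene Itgav (18976 ± 4581). Thy1 was above the limit in samples 1 and 4 with 2374 and 3155 and below it in sample 5 with 757, and Eng was not detected.

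Haematopoietic stem and progenitor markers had 3 of 17 genes detected. The transcription factor genes Mecom, Meis1 and Gata2 (4113 ± 828) were detected, and Kit, Cd34 and Flt3 were not. Mecom and Meis1 were each detected by 1 of 3 probe sets and Gata2 by 1 of 2. Neural stem and progenitor markers had 2 of 15 detected, and these were the intermediate filament genes Nes (1492 ± 366) and Vim (70921 ± 31870), while Sox1 and Pax6 were not detected. Satellite cell and myoblast markers had 6 of 19 detected, including Eya4, the heparan sulfate proteoglycan gene Sdc4 (9537 ± 2517) and the receptor gene Met. The myogenic regulators Pax7, Myod1 and Myf5 were not detected, with Myod1 at 549 ± 269.

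The interstitial matrix list was called high, with 24 of 29 genes detected where the central 95% of random lists had 6 to 16 (adjusted permutation p = 0.00128). Col1a1 read 18229 ± 11941 and Col3a1 29987 ± 26084, while Lum, Thbs1 and Mfap5 were not detected. Basement membrane genes (6 of 17 detected), fibroblast and mesenchyme regulators (8 of 26) and smooth muscle and actin genes (13 of 25) lay within the random range. The detected basement membrane genes included Col4a1 (6719 ± 2119), Col4a2, Lamb1, Nid1 (8628 ± 3143), Hspg2 and Col18a1. Among the regulators of mesenchyme, Prrx1, Snai2, Tcf4, Zeb1 and Foxp1 were detected and Twist1, at 1209 ± 420, was not. In the smooth muscle list Acta2, the actin of contractile cells and myofibroblasts, was detected, by 1 of its 3 probe sets. Tagln, Cnn1, Myh11, Myocd and Myl9 were not, and Tagln, Cnn1 and Myl9 had 1 probe set each.

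Genes of the differentiated cells that 10T1/2 can give rise to were mostly below the limit. Skeletal muscle differentiation had 0 of 26 genes detected (adjusted permutation p = 0.00427), with Myog at 254 ± 177, Ckm at 554 ± 222 and Acta1 at 68.8 ± 27.4. Cartilage differentiation had 0 of 20 detected (adjusted permutation p = 0.00240), with Sox9 at 783 ± 163, Col2a1 at 1012 ± 901 and Acan at 622 ± 240. Adipocyte genes (3 of 19) and bone genes (1 of 15) lay within the random range. The early adipogenic factor gene Ebf1, the desaturase gene Scd1 (4903 ± 3282) and Dgat2 were detected, and Pparg and Adipoq were not. Fabp4 was above the limit in sample 5 only, with 266, 250 and 2991 in samples 1, 4 and 5. Sp7 was not detected, and the bone list's detected gene was Atf4, a regulator that is also active in many other cells.

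Markers of other cell types were also rare. Endothelial markers had 0 of 20 genes detected (adjusted permutation p = 0.00240), with Pecam1 at 227 ± 101, Cdh5 at 355 ± 83.7 and Kdr at 1096 ± 402. Neuron and glia markers had 1 of 20 (adjusted permutation p = 0.00213), while Tubb3, Map2 and Gfap were not detected. The detected gene was the glial regulator gene Sox10 (1358 ± 166), from 1 of its 3 probe sets. Epithelial and keratinocyte markers had 2 of 22, below the random range but not after adjustment (permutation p = 0.0366, adjusted permutation p = 0.0836). Its detected genes were Elf3 (1431 ± 214) and Epcam, which was detected by a MOE430B probe set only, and Cdh1 and Krt18 were not detected. Leukocyte and macrophage markers had 2 of 20, Csf1r (1193 ± 28.6) and Cd14 (2958 ± 1051), within the random range, and Ptprc and Cd68 were not detected. Csf1r was detected by 1 of its 3 probe sets, close to the limit. The calls of cartilage, endothelial, and neuron and glia genes ended when most probe sets of a gene had to be detected or the median signal was tested, and that of epithelial genes under the first of these rules and at the 99th percentile limit.

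Metabolic and secretory programmes stood at the other end. All 25 measured genes of oxidative phosphorylation were detected, against a mean of 8.93 in random lists, with Cox4i1 at 18391 ± 2308, Ndufs1 at 2248 ± 675 and Atp5b at 13155 ± 8387. Of cytosolic ribosomal protein genes 19 of 20 were detected, including Rps6 (2255 ± 54.9) and Rplp0 (46294 ± 15111), and Rps16 was not. Endoplasmic reticulum chaperone and secretion genes had 19 of 22 detected, among them Hspa5 (37339 ± 5743), Hsp90b1 and P4hb (36286 ± 4775), but not Atf6, Pdia4 or Sdf2l1. Cholesterol and sterol synthesis had 15 of 18, with Sqle at 4116 ± 768 detected and Fdps, Msmo1 and Sc5d not. These 4 lists had the same adjusted permutation p of 0.00128, from a permutation p of 0.0002, the smallest the random lists can give. Glycolysis had 14 of 19 (adjusted permutation p = 0.00448), including Ldha (24811 ± 9557), Pgk1 (127360.0 ± 21961) and the glucose transporter gene Slc2a1, and not Slc16a3, Egln3 or Car9. The p53 and senescence list had 11 of 16 (adjusted permutation p = 0.00587). Cdkn1a, the cell cycle inhibitor downstream of p53, read 12983 ± 2193, while Cdkn2a, Perp, Bbc3 and Gadd45a were not detected.

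Hox genes, which record position along the body axis, had 1 of 32 detected (adjusted permutation p = 0.00465). This was Hoxa5 (6283 ± 864), whereas Hoxc8 (110 ± 50.8) and Hoxd9 (413 ± 72.4) were not detected. The other programmes lay within the random range. Cell cycle and mitosis had 15 of 29 detected, with Cdk1 detected and Mki67, Bub1, Cdc6 and Cdc45 not. Immediate early and serum response genes had 10 of 25, including Egr1 (4582 ± 739), Jun, Cxcl1, Fosl2 and Klf6, and not Fos. Interferon and antigen presentation genes had 3 of 22, Ifi35, B2m and Irf1, and not Ifit1 or H2-K1. Imprinted genes had 7 of 22, among them Grb10 (24579 ± 6589), the noncoding RNA gene Meg3 and Ndn, with Igf2 and Dlk1 not detected. TGF-beta and BMP signalling had 16 of 27, including the receptor genes Tgfbr2 and Bmpr1a (3089 ± 231), and not Tgfb1, Nog, Acvr2a or Ltbp1. Wnt and Hedgehog signalling had 9 of 28, with Ctnnb1, Fzd1, Gli3 and Fzd2 detected and Gli1 and Ptch1 not. Notch and FGF signalling had 8 of 26, with Rbpj, Fgf7 and Notch2 detected and Notch1, Fgf2 and Fgfr2 not.

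**Figure D1:**
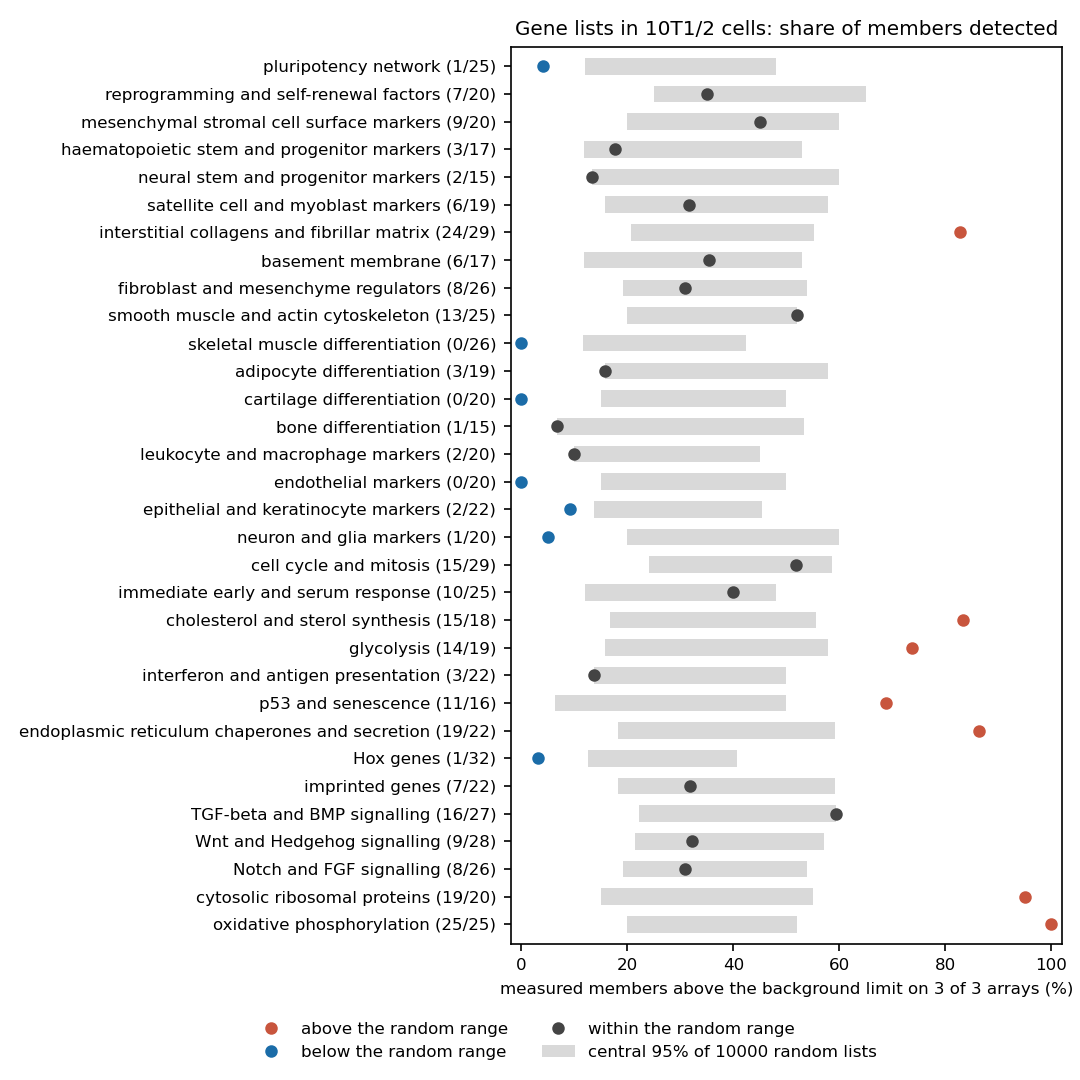
Percent of each list's measured genes above the background limit on 3 of 3 arrays (points, with detected and measured genes in parentheses) beside the central 95% of 10000 random lists (bars). Oxidative phosphorylation (25 of 25), ribosomal proteins (19 of 20) and interstitial matrix (24 of 29) lie above the bars, and pluripotency (1 of 25), skeletal muscle (0 of 26) and Hox genes (1 of 32) below them.

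The brightest probe sets of MOE430A belonged to the translation factor gene Eef1a1, Lgals1, Rpl41, Tpt1, Rps2, Rps18, Rps28, Rps3, Uqcrb and Npc2. Those of MOE430B belonged to Sf1, Snai2, Rpl22, Psap, Sod1, Mrps6, Map1lc3a, Fnta, Arl1 and Bms1. All of the latter but that of Psap had names ending in _s_at or _x_at, the endings counted here as able to match several transcripts. So did those of Rpl41, Rps2, Rps18 and Rps28. Those of Psap, Lgals1, Tpt1, Rps3, Uqcrb and Npc2 ended in _a_at, which was not counted, so they were not shown to match a single transcript. In all, 14 of 32 lists lay outside the random range, 7 high and 7 low, where 1.6 would by chance, and 13 did after adjustment. Resampling the background probe sets moved the detected probe sets from 6196 to between 4189 and 7550 on MOE430A and from 2770 to between 2545 and 4761 on MOE430B, and requiring most of a gene's probe sets left 2774 detected genes. Without sample 1 the cell cycle list was called high and the neural stem, adipocyte, bone, leukocyte and interferon lists low. Without sample 4 the immediate early list was called high and the neural stem and bone lists low, and without sample 5 TGF-beta and BMP signalling high and the adipocyte list low. By the median signal the cell cycle, smooth muscle and immediate early lists were called high and the neural stem and adipocyte lists low. Smooth muscle genes were also called high when most probe sets had to be detected, TGF-beta and BMP signalling without probe sets that can match several transcripts, and the adipocyte and interferon lists low at the 90th percentile limit. With detection on 2 of 3 arrays, chosen for the lists after seeing the data, cell cycle and TGF-beta and BMP genes were called high and the neural stem, adipocyte and leukocyte lists low.

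The second comparison asked how far gene groups varied between the 3 samples of this one line. Matrix genes were much lower in sample 5 and cell cycle genes lower in sample 1. On MOE430A the 24 detected matrix genes had a median deviation of -1.87 (log2) in sample 5 from the mean of the other 2, which is 3.65-fold lower, with 22 of 24 genes lower (adjusted permutation p = 0.00270). Col1a1 read 31161, 15904 and 7621 in samples 1, 4 and 5, Col1a2 183221, 161044 and 43699, and Col3a1 58322, 24663 and 6976. The same list was higher in sample 1 (1.04, 2.06-fold, 20 of 24 genes) and in sample 4 (0.85, 1.80-fold, 18 of 24), each at the same adjusted permutation p. With sample 5 left out, the matrix list differed by 0.36 between samples 1 and 4, with sample 4 the lower, and was inside the random range.

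The 13 detected genes of cell cycle and mitosis were all lower in sample 1, by 2.42-fold at the median (-1.27, adjusted permutation p = 0.00270). The median was higher in samples 4 (0.63, 11 of 13 genes, adjusted permutation p = 0.00360) and 5 (0.63, 11 of 13, adjusted permutation p = 0.0245). Cdk1, the kinase that drives entry into mitosis, read 1809 in sample 1, 10433 in sample 4 and 4459 in sample 5. Proliferation marker Mki67 read 595, 3678 and 3164, and the spindle checkpoint kinase gene Bub1 36.5, 822 and 1293. Neither was among the 13, since Mki67 was below the limit in sample 1 and Bub1 in samples 1 and 4. With members kept by their mean signal, so that genes low in 1 sample stayed in, 22 of 22 were lower in sample 1. The median was then at least 3.08-fold lower (-1.62), with signals below the limit raised to it, an alternative chosen after seeing the data. With sample 1 left out, the list differed by 0.31 between samples 4 and 5, with sample 5 the lower, inside the random range.

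Further lists moved less. In sample 5, smooth muscle and actin genes were 1.71-fold lower at the median (-0.78, 8 of 13 genes lower, adjusted permutation p = 0.0245), although inside the random range against sample 4 alone (-0.40). Acta2 read 69179, 81188 and 4604 in samples 1, 4 and 5. This was the only 1 of its 3 probe sets detected, and it can match several transcripts. Endoplasmic reticulum chaperones were 1.43-fold higher in sample 5 (0.52, 13 of 19 genes higher, adjusted permutation p = 0.0245). In sample 1, glycolysis was 1.63-fold lower (-0.70, 10 of 14 genes lower, adjusted permutation p = 0.00360) and cholesterol synthesis 1.30-fold lower (-0.38, 13 of 14 lower, adjusted permutation p = 0.0347). Wnt and Hedgehog genes were 1.61-fold higher in sample 1 (0.69, 6 of 6 genes, adjusted permutation p = 0.0245), reprogramming factors 1.62-fold higher (0.70, 6 of 7, adjusted permutation p = 0.0245) and Notch and FGF genes 1.47-fold higher (0.55, 7 of 8, adjusted permutation p = 0.0347). The call of the reprogramming factors ended without sample 4, without sample 5, with no filter and with lower signals raised to the limit, and that of Notch and FGF genes without sample 4. In sample 4, smooth muscle genes were 1.32-fold higher (0.40, 9 of 13, adjusted permutation p = 0.0347), a call that ended with sample 1 or sample 5 left out and with no filter.

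Immediate early genes lay outside the random range in sample 5 (0.53, 7 of 8 genes higher) but not after adjustment (adjusted permutation p = 0.0794). With members kept by their mean signal, an alternative chosen after seeing the data, 13 of 14 were higher in sample 5 (adjusted permutation p = 0.00127). The median was 2.08-fold higher (1.06) with signals below the limit raised to it. Cxcl1, a chemokine gene of this list, read 11617, 7143 and 169471 in samples 1, 4 and 5 on MOE430B. Basement membrane, p53 and senescence, TGF-beta and BMP, and oxidative phosphorylation genes lay inside the random range in every sample. In all, 22 of 54 combinations of list and sample lay outside it, where 2.7 would by chance. With a sample left out, 5 to 8 lists did, each list then counted once. On MOE430B only TGF-beta and BMP signalling, with 6 genes, had enough members, and it stayed inside the range. The deviations of the 3 samples are tied to one another, since each is taken from the mean of the other 2.

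**Figure D2:**
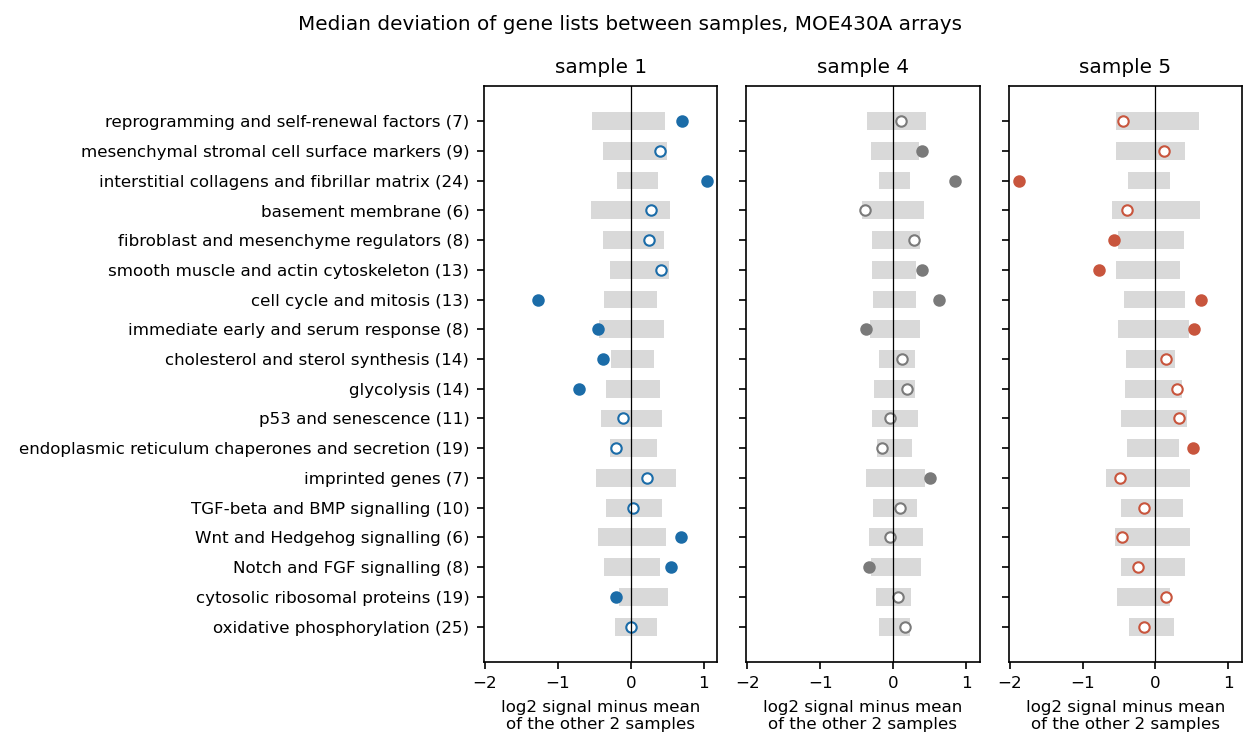
Median log2 signal of each list's detected genes on MOE430A minus the mean of the other 2 samples, for samples 1, 4 and 5 (points, filled outside the random range), beside the central 95% of random lists matched on signal (bars); the number of genes is in parentheses. Matrix genes stand at -1.87 in sample 5 and cell cycle genes at -1.27 in sample 1.

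The most variable detected probe sets of MOE430A were 2 of Atp1b1, a subunit of the sodium pump (33.5-fold and 33.4-fold between the highest and lowest sample), and 1 each of Ogn (29.2-fold), Col6a2 (24.0-fold), Ccn3 (23.3-fold), Fbln5 (21.7-fold), Nrep, Acta2 (17.6-fold), an unnamed probe set and the metalloproteinase inhibitor gene Timp3 (16.4-fold). On MOE430B they were 2 of Cxcl1 (23.7-fold and 14.1-fold) and 1 each of Meg3 (12.1-fold), Arhgap11a, Mcm5, a subunit of the replicative helicase (9.05-fold), Btbd11, Cdca8, Adm, Gchfr and Adamts5. The typical spread was far smaller, with a median SD of 0.35 (log2) over the detected probe sets of MOE430A and 0.31 on MOE430B, or 1.27-fold and 1.24-fold, and 0.53 and 0.66 over all probe sets. Pearson correlations of log2 signal across probe sets were 0.885, 0.862 and 0.893 for samples 1 and 4, 1 and 5, and 4 and 5 on MOE430A, and 0.752, 0.748 and 0.769 on MOE430B. Probe sets with a mean above the limit and a range over 4-fold, a count chosen after the data were seen, numbered 458 of 7634 on MOE430A and 159 of 3933 on MOE430B. Sample 5 was the farthest from the other samples in 274 of the 458, sample 1 in 160 and sample 4 in 24. On MOE430B these were 73, 71 and 15. Above the limit on every array, the counts were 214 and 49, and with a sample left out 103 to 386 and 44 to 99.

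The third comparison asked whether the differences between samples were shared by the 2 array designs, which a fault of a single array would not give. Differences of the RNA and of its labelling could both be shared, and were not told apart. Meg3, an imprinted noncoding RNA, had the largest shared range, 11.7-fold, with 34712, 16760 and 3058 in samples 1, 4 and 5 on MOE430A and 60631, 42645 and 5011 on MOE430B. Prkg2, a cyclic GMP dependent kinase gene, went the other way, with 1167, 5097 and 16103 on MOE430A and 9338, 34030 and 64637 on MOE430B. Ebf1 (5.04-fold), the aggrecan-cleaving protease gene Adamts5 (4.72-fold) and the DNA repair gene Ercc1 (4.22-fold) followed. Across 341 genes the deviations on the designs correlated with Pearson r = 0.42, 0.31 and 0.62 in samples 1, 4 and 5, and Spearman rho = 0.31, 0.29 and 0.57. The deviations had the same sign on both designs in all 3 samples in 98 of the 341 genes (28.7%), against a mean of 58.1 (17.0%) and a central 95% of 45 to 72 when gene labels were permuted. The 3 permutation p-values were 0.0001 for each measure, the smallest 10000 permutations can give, and the same after Benjamini-Hochberg adjustment over the samples. Genes are not independent replicates, and the 3 deviations of a gene add up to 0. Over all 3729 genes on both designs, dim ones included, r was 0.11, 0.05 and 0.14, with sample 5 left out r was 0.24 over 412 genes, and with sample 1 left out 0.51 over 426.

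**Figure D3:**
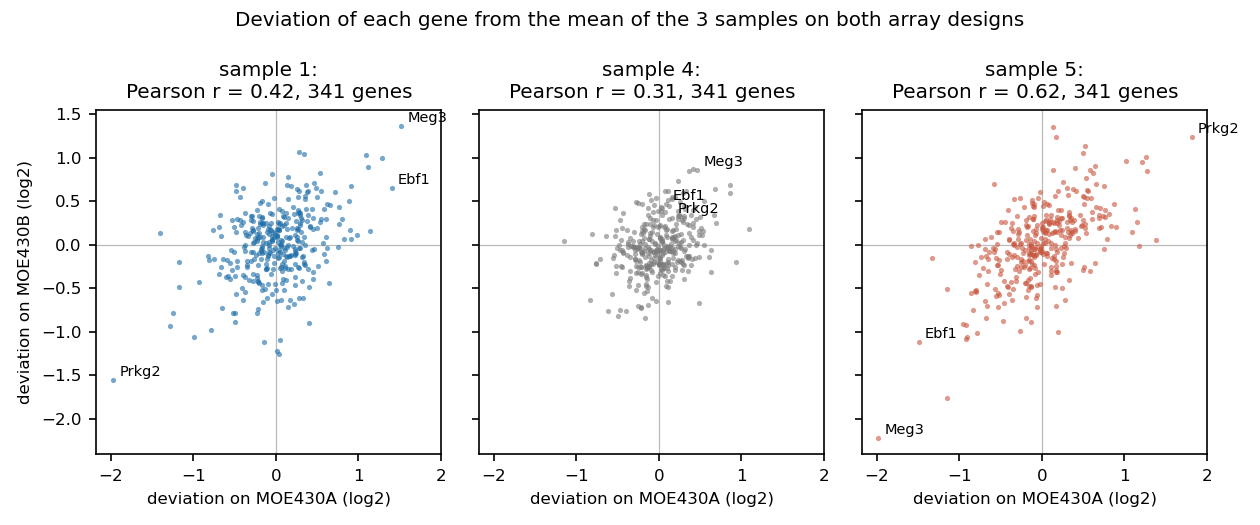
Deviation of each of 341 genes from the mean of the 3 samples (log2) on MOE430A (horizontal axis) and MOE430B (vertical axis), for samples 1, 4 and 5. Points follow the diagonal most in sample 5 (r = 0.62), where Meg3 lies lowest on both designs and Prkg2 highest on MOE430A.

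Control transcripts gave the state of the RNA and its labelling. The 3' to 5' ratio of Gapdh, mean of both arrays, was 24.0 in sample 1, 14.5 in sample 4 and 11.1 in sample 5, and that of beta-actin 18.9, 8.90 and 9.72, so sample 1, with the low cell cycle genes, had the highest ratios of both. With the middle probe set in place of the 5' one, the Gapdh ratios were 6.93, 3.39 and 2.78 and those of beta-actin 9.31, 4.28 and 4.51. Hybridisation controls, added to each target mix, were 1.80-fold lower on MOE430A and 1.57-fold lower on MOE430B in sample 5, the sample with the low matrix genes. They were 1.42-fold and 1.64-fold higher in sample 4, and 1.32-fold and 1.01-fold higher in sample 1, so sample 5 was not alone in deviating. The control probe set for the B1 repeat was 4.23-fold lower in sample 5 on MOE430A and 3.81-fold lower on MOE430B. The brighter of the 2 for the B2 repeat was 1.27-fold and 1.23-fold lower there. The dimmer one stood at 0.39 (log2) on MOE430A and -0.29 on MOE430B. The MOE430A array of sample 5 was also the only one of the 6 washed on a second fluidics station. The 100 probe sets common to both designs, controls left out, read higher on MOE430B, with a median difference of -1.91 ± 0.15 (log2, SD, n = 3), or 3.76-fold. Their deviations in samples 1, 4 and 5 correlated between the designs with r = 0.61, 0.53 and 0.71 across probe sets, which are not independent replicates.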

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

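The alternatives added to those fixed before the data were examined, which were chosen after the results were seen, are detection on 2 of 3 arrays for the lists, the filter on mean signal, with and without lower signals raised to the limit, samples left out between samples, and those on 4-fold differences and added lists. Most results kept their direction and side of the threshold: 878 of 918 alternatives for named genes against the limit (9 weaker, 31 stronger), 255 of 288 for the lists' detected members (8 weaker, 25 stronger), 320 of 378 for list deviations (16 weaker, 34 stronger) and 34 of 36 for the added lists (2 weaker). Of the list deviations 8 reversed. The median deviation in sample 4, with 1 other sample left out, ran from -0.36 to 1.82 for matrix genes, from -0.30 to 0.22 for stromal surface markers, from -0.018 to 0.40 for smooth muscle genes, from -0.19 to 0.80 for imprinted genes and from -0.57 to 0.058 for Notch and FGF genes (0.0074 with no filter). It ran from -0.31 to 1.52 for cell cycle genes in sample 5 and from -0.80 to 0.072 for immediate early genes in sample 1. Requiring most probe sets left 2774 detected genes, since fewer genes can pass. The median SD was 0.53 on MOE430A and 0.66 on MOE430B with no filter, which adds dim probe sets, and 0.35 on MOE430B with a filter on the mean, which adds those low in 1 sample. With a sample left out it was 0.24 to 0.33 and 0.23 to 0.26. Lists outside the random range numbered 5 to 8 with a sample left out, where each list counts once. Probe sets over 4-fold numbered 214 and 49 when above the limit on every array, which removes genes that fell in 1 sample, and 103 to 386 and 44 to 99 with a sample left out. Scaling by the 75th percentile gave -1.55 between the designs; the cause was not tested. Ratios of 3' to middle probe sets, which span less of the transcript, were 6.93, 3.39 and 2.78 for Gapdh and 9.31 for beta-actin in sample 1. Signal over background limits the rest: the limit on MOE430B rests on 19 probe sets, so genes near it are uncertain. The planned limit from poly-A controls was not run, since 11 of the 12 probe sets of these controls on MOE430A and 12 of 12 on MOE430B were above the limit on every array. No paired analysis was possible because no test compared the levels of 2 groups; the array designs were matched by sample number to correlate deviations and describe their offset.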

Other observations

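All tests and gene lists in this part, except the ribosomal protein list, were chosen only after the results were seen. On MOE430A the 16 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, were 2.39-fold higher at the median in sample 5 than in the mean of the other 2 (1.25 log2, 16 of 16 genes, adjusted permutation p = 0.00048) and 2.09-fold lower in sample 1 (-1.06, 16 of 16 lower). Rars read 2223, 4518 and 12972 in samples 1, 4 and 5. Genes known to respond to amino acid shortage through the transcription factor Atf4 went the same way, with 2.82-fold higher values in sample 5 (16 of 16 genes, adjusted permutation p = 0.00048) and 2.07-fold lower values in sample 1 (-1.05, 14 of 16 lower). Asns, which makes asparagine, read 1466, 4714 and 10476, the glutathione-degrading enzyme gene Chac1 1295, 1883 and 6530, and Atf4 itself 3810, 6257 and 17914. Nucleolar factors that assemble ribosomes were 1.72-fold higher in sample 5 (0.79, 30 of 36 genes, adjusted permutation p = 0.00048) on MOE430A and 1.65-fold higher (0.72, 10 of 10, adjusted permutation p = 0.0072) on MOE430B. Nucleolin (Ncl) read 3021, 4846 and 16847, and Dkc1, which modifies ribosomal RNA, 5312, 7575 and 35129 on MOE430B. In sample 4 the medians of the 3 lists on MOE430A were -0.25, -0.46 and -0.31. With signals below the limit raised to it, those in sample 5 were 2.18-fold, 2.79-fold and 1.62-fold higher. The planned list of cytosolic ribosomal proteins passed the adjusted test in no sample, with 0.14 in sample 5 (10 of 19 genes higher, adjusted permutation p = 0.221) and -0.21 in sample 1 (adjusted permutation p = 0.0828).

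Single genes were also picked for a large deviation of 1 sample where the other 2 lay within 2-fold. Signals below the limit were raised to it, so that the folds given as at least are lower bounds. In sample 5 the chemokine gene Ccl2 was at least 13.7-fold higher (367, 267 and 14237), and Gadd45a, the growth factor gene Hbegf and the AP-1 gene Fosl1 were at least 6.47-fold, 8.39-fold and 5.77-fold higher. The stromal surface gene Cd248 was at least 6.27-fold lower there, Bmp4 and its target Id2 each at least 2.45-fold lower, and the matrix gene Postn 9.17-fold lower. In sample 1 the thymidine kinase gene Tk1 was at least 3.90-fold lower, the centromere gene Cenpa at least 2.97-fold and the mitotic kinase gene Aurkb at least 3.57-fold lower, and Bub1b at least 9.16-fold lower on MOE430B. Higher in sample 1 were Igfbp4 (13.2-fold), Clu (at least 7.71-fold), Selenop (7.30-fold) and the gelatinase gene Mmp2 (4.69-fold). In sample 4 Pdk4 was at least 3.99-fold higher, Epcam 4.57-fold higher on MOE430B and Sema3c at least 4.93-fold lower on MOE430B. Epcam read 31382, 139544 and 29693 on MOE430B, while its MOE430A probe set read 47.4, 39.1 and 39.5.

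The low matrix genes of sample 5 could stem from a fault of its MOE430A array or of the station that only this array passed. Against this as the whole cause, 17 of 19 genes, or 89.5% (exact 95% interval 66.9 to 98.7), went the same way on MOE430B. They were those of all genes, not matrix genes alone, that stood farthest apart in sample 5 on MOE430A and could be followed. The interval takes genes as independent, which they are not, so it can be too narrow and only describes these genes. The 3 matrix genes followed on MOE430B, Sparc, Thbs2 and Mfap2, were all lower in sample 5 than the mean of the other 2. Their median was -1.18 log2 (SD 0.66), with random lists at -0.85 to 0.82. Against sample 4 alone, Sparc showed no fall there (-0.19 and -0.16 from the mean of the 3 samples in samples 4 and 5). Mfap2 read 1950 and 1891, below the limit in both. For cells of another listed type, stromal and smooth muscle cells aside, the highest share of a list above the limit in sample 5 was 31.6%. This was 6 of 19 satellite cell and myoblast genes, the same as in samples 1 and 4. Leukocyte markers were at 25% in sample 5 (15% and 10% in samples 1 and 4) and epithelial markers at 18.2% (9.09% and 13.6%). The haematopoietic, neural stem, cartilage, bone, endothelial, and neuron and glia lists had their lowest shares there. What share such cells would give was not measured, and cells making up a part of the sample could give less, so these shares cannot decide. Stromal or smooth muscle cells of another kind and fibroblasts cannot be told apart here, since 55% of stromal surface markers and 52% of smooth muscle genes were above the limit in sample 5, against 55% and 60% in sample 1, and a mislabelled sample was not tested. No biological explanation was tested, since the design names no difference between the samples.

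The low cell cycle genes of sample 1 could come from a fault of its MOE430A array or from a larger loss of 5' sequence. A fault of that array as the whole cause is argued against, since the 4 cell cycle genes followed on MOE430B were all lower in sample 1. Their median was -2.38 log2 (SD 2.25), below the central 95% of random lists (-0.70 to 0.54), without signals below the limit raised to it. Bub1b read 408 in sample 1, below the limit, and Mcm5, above it on every array, was 7.56-fold lower there. For loss of 5' sequence, the Gapdh and beta-actin ratios were highest in sample 1, as were those of the bacterial controls phe (23.6 against 13.2 and 9.93) and lys (8.03 against 7.84 and 5.09) and the 3' to middle ratios of all 4 bacterial controls (17.9 against 10.8 and 9.63 for thr), but not the 3' to 5' ratios of dap (2.64 against 3.23 and 2.25) and of thr on MOE430B (54.0 against 105 and 87.4). Within cell cycle genes the weaker probe sets fell less than the brightest, by 0.11 log2 at the median (SD 0.61, 3 of 8 genes the other way). Over all 1308 genes the weaker ones fell further in sample 1 (-0.17, against 0.067 and 0.10 in samples 4 and 5). Loss of 5' sequence would have them fall further only where they lie nearer the 5' end, which was not checked. For this reason and with this spread, that loss and a change of the genes themselves cannot be told apart. No biological explanation was tested.

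The high 3' to 5' ratios of Gapdh and beta-actin could reflect breakdown of the cells' RNA. The bacterial poly-A controls, which do not come from the cells, had high ratios as well. Of their 12 mean ratios 10 were above 3, with 5' signals below the limit raised to it. They ran from 2.25 for dap in sample 5 to 88.9 for thr in sample 4. What ratio these probe sets give for whole transcripts is not known here, so the count cannot decide whether breakdown was the whole cause. Loss of 5' sequence during labelling stays open and was not tested on its own. No biological explanation was tested.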
